A study of Caenorhabditis elegans with 18 samples.

How the data were processed

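Polyadenylated RNA of whole Caenorhabditis elegans larvae in the second larval stage was sequenced in 18 libraries. Per the labels, 3 strains were sampled at 20 °C and after 30 min at 34 °C, with 3 replicate libraries in each of the 6 groups. The strains were the wild type N2, the mutant hsf-1(sy441), which carries a premature stop in the gene of the heat shock transcription factor, and hsf-1(sy441) animals with the transgene rmSi1[hsf-1::gfp] and the mutation unc-119(ed9), called the hsf-1::gfp transgene strain here. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries.

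Per the submitters' processing notes, the tools were TopHat2 and Cuffdiff and the genome build was ce10. The versions, the gene annotation, the trimming of reads and the options of both tools were not given in the sources used here. Per the file headers, the deposited table of read groups holds expected counts of fragments per gene and library before scaling, and the same deposited table holds FPKM values scaled between libraries by the authors. Of the fragment values, 92.43% were whole numbers, and rounding the others changed no library total by more than 7e-05%. The deposited test tables give the authors' log2 ratios of FPKM between groups and the authors' p_value and q value columns from Cuffdiff. A further deposited table lists FPKM per group and p values for heat shock in N2 and holds genes past the authors' threshold alone. The replicate numbers of the deposited table start at 0 and those of the labels at 1, and they were matched in their order within each group.

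The table covered 20389 genes, of which 19879 (97.5%) were matched to a gene name by their identifier. For 114 genes Cuffdiff gave a failed estimate in at least 1 library, and these genes, which held between 6.11% and 7.75% of the fragments of a library, were left out. They included hsp-16.1, hsp-16.11, F44E5.4 and F44E5.5. Cuffdiff merges overlapping or neighbouring genes into 1 locus, and values of genes in a shared locus are uncertain where reads could not be assigned to 1 of them. The depth ranged from 16.1 to 34.7 M fragments per library. Reads were amplified by PCR without molecular identifiers as far as the labels state, so intervals and floors cover counting error only.

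Counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 6 groups, which left 14219. Libraries were scaled with TMM factors between 0.85 and 1.239. A quasi-likelihood model with robust dispersion had 1 mean per group, and the biological coefficient of variation was 25.3%. Levels are given in CPM, counts scaled to library size with TMM factors, as mean ± SD, n = 3. Heat shock was tested within each strain, strains were tested against each other at each temperature, and the differences between strains in the heat shock response were tested as interaction terms. P-values were adjusted with the Benjamini-Hochberg method within each comparison and called at 0.05. Every adjusted p for a gene is from edgeR's quasi-likelihood test unless another tool is named. Where all libraries of a group had 0 fragments, folds were bounded with a floor of 3 fragments over the group.

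Genes were named by a rule fixed before the data were examined. It takes hsf-1 and unc-119 in each comparison. It adds the 6 genes with the largest rise and the 6 with the largest fall at 20 °C and in heat shock, and 4 and 4 at 34 °C and for interactions. Those genes had to be called, to reach 10 CPM in the higher group and, except for interactions, to have every library of one group above every library of the other. The rule also takes up to 4 members of each gene list described, and the inducible heat shock proteins in the heat shock comparisons. Other genes are named as chosen after their values were seen.

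Before the data were examined 28 gene lists were fixed from general knowledge, and 26 with at least 5 measured members were tested. The test was camera of limma 3.58.1 with a preset correlation of 0.01 between genes. Calls were repeated with a correlation estimated from the data and with fry. Camera's p-values were adjusted over the 26 lists within a comparison. Counts of called members are given over all genes tested and adjusted over the list alone.

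The pipeline was tested on simulated data of heat shock in N2, in 10 simulations with 200 changed genes each. Over these it recovered 24.2% of genes changed 1.5-fold, 72.8% of those changed 2-fold and 89.2% of those changed 4-fold, the last between 83.3% and 95.5% in single simulations. It called 4 to 9 genes per simulation that were not changed. Changed genes were drawn only from those with a mean above 5 CPM, so recovery below that level was not tested. Genes were simulated independently of each other, so the simulations lacked the axis of replicate differences described below. Alternatives fixed before were size factors by relative log expression (RLE) in edgeR and the Wald test of DESeq2 1.42.0. They also included no filter on low counts, a filter at 5 CPM in 3 libraries, limma on log2 FPKM with a pseudocount of 1 or 0.1, and fits of the compared groups alone. Others were stricter thresholds, replicate numbers as a block, and each library left out in turn. A further alternative, called the composition scaling here, took library sizes without the inducible heat shock genes and the 50 most abundant genes and used no TMM. A score for the leading axis of replicate differences as a covariate, and the list tests with a block or without replicate 3 of the transgene strain at 20 °C, were chosen after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.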

Results

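The series measured gene expression in whole larvae of 3 strains of Caenorhabditis elegans, at 20 °C and after 30 min at 34 °C. The strains were N2, hsf-1(sy441), whose heat shock transcription factor HSF-1 lacks part of its activation domain, and hsf-1(sy441) animals that also carried an hsf-1::gfp transgene. Each of the 6 groups had 3 libraries with a depth of 16 to 34.7 M fragments, and 14219 genes were tested. The design asks which transcripts depend on hsf-1 in larval development and which in heat shock. Levels are in CPM as mean ± SD, n = 3, and positions are in ce10. The scaling of the libraries bears on every direction given here. With the composition scaling the median log2 fold change of all genes moved by −0.15, −0.24 and −0.17 in heat shock of N2, hsf-1(sy441) and the transgene strain. It moved by 0.21 for hsf-1(sy441) against N2 and 0.12 against the transgene strain at 20 °C, and by 0.13 for hsf-1(sy441) against N2 at 34 °C.

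The first question was what 30 min at 34 °C changed in N2. The level of hsf-1 (Y53C10A.12, chromosome I, 11953502 to 11961977) was 39.5 ± 2.17 CPM before and 33.6 ± 4.25 CPM after heat shock, a log2 fold change of −0.23 with an adjusted p of 5.8e-02. This p ranged from 6.4e-03 to 0.22 over the alternatives, and it was 2.2e-02 with replicates as a block. The Hsp70 gene hsp-70 (C12C8.1, chromosome I, 9317728 to 9327204, a locus shared by 2 genes) rose from 0.431 ± 0.142 to 1170 ± 229 CPM, which was 2730-fold. The small heat shock protein genes hsp-16.41 (Y46H3A.2) and hsp-16.2 (Y46H3A.3) lie in 1 locus merged with 2 other genes on chromosome V, from 1799725 to 1809467. Their levels went from 0.556 ± 0.463 to 3090 ± 239 CPM and from 0.691 ± 0.688 to 3210 ± 156 CPM. Their log2 fold changes of 12.49 and 12.24 became 13.35 and 13.39 without replicate 3 of N2 at 20 °C. R11A5.3 rose from 0.392 ± 0.239 to 471 ± 145 CPM. Of the 9 inducible heat shock protein genes 4 were measured and all 4 rose, and 4 others had failed estimates. The fourth measured gene, hsp-16.48, had a single fragment at 20 °C and 0.595 ± 0.194 CPM at 34 °C, a ratio with a counting interval of 7.64 to 1680. It had 6, 11 and 12 fragments at 34 °C, and its level is uncertain if reads were shared with near-identical hsp-16 copies, which was not tested.

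Among 17 constitutive cytosolic chaperone genes 9 rose and 1 fell, with 10 up and 1 down adjusted over the list alone. The list's median log2 fold change was 0.36, with a camera adjusted p of 2.6e-08 and an adjusted p = 0.056 with an estimated correlation. The Hsp70 co-chaperone gene hsp-110 (C30C11.4, chromosome III, 8443832 to 8446846) rose 15-fold, from 381 ± 18.1 to 5730 ± 450 CPM. The level of hsp-90 rose from 2490 ± 156 to 8880 ± 427 CPM, that of the BAG domain gene unc-23 from 106 ± 9.04 to 601 ± 59.2 CPM, and that of the J-domain gene dnj-13 from 253 ± 44.4 to 1130 ± 113 CPM. These last 3 genes share their loci with other genes. Of 13 CCT chaperonin and prefoldin genes, whose products fold actin and tubulin, 10 rose over all genes and adjusted over the list alone, but 4 with the composition scaling (adjusted p = 0.0034, and adjusted p = 0.44 with an estimated correlation). Of 9 other small heat shock protein genes 5 rose by both adjustments, or 3 with the composition scaling (adjusted p = 0.0087, and adjusted p = 0.51 with an estimated correlation). Their member hsp-12.6 went from 0.0749 to 5.8 ± 3.95 CPM, with a log2 fold change of 6.26 that ran from 5.61 to 6.95 without 1 library. That of hsp-16.21 fell from 7.19 to 2.4 (adjusted p = 6.0e-02) without replicate 3 of N2 at 34 °C. The call of hsp-12.1 was lost in 5 alternatives, while those of hsp-12.3 and hsp-12.6 were kept in all. The endoplasmic reticulum Hsp70 gene hsp-4 (F43E2.8) rose 8.15-fold, from 185 ± 17.7 to 1500 ± 229 CPM. Its list of 19 stress and folding genes had 2 genes up and 6 down, 2 and 7 adjusted over the list alone, with an adjusted p of 0.64.

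Genes of translation and mitochondria also rose in N2. Of 73 cytosolic ribosomal protein genes 67 rose, 68 adjusted over the list alone, with a median log2 fold change of 0.80 (adjusted p = 3.4e-32, and adjusted p = 0.056 with an estimated correlation). The level of rps-8 rose from 4390 ± 177 to 8530 ± 338 CPM. Of 64 mitochondrial ribosomal protein genes 49 rose, 53 adjusted over the list alone (adjusted p = 9.7e-14, and adjusted p = 0.44 with an estimated correlation). Of 38 respiratory chain and ATP synthase genes 27 rose, 30 adjusted over the list alone (adjusted p = 2.8e-07, and adjusted p = 0.41 with an estimated correlation). Among 37 genes of glutathione S-transferases and the oxidative response 15 rose and 1 fell, 16 and 1 adjusted over the list alone, and 7 and 1 with the composition scaling (adjusted p = 0.0034, and adjusted p = 0.17 with an estimated correlation). Their member trx-2, a thioredoxin gene, rose from 69.4 to 115 CPM.

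Of 32 neuron markers 21 fell and 3 rose in N2, 22 and 3 adjusted over the list alone, with a median log2 fold change of −0.55 (adjusted p = 5.4e-07, and adjusted p = 0.29 with an estimated correlation). The gene of peptide amidation pgal-1 (F21F3.1) went from 207 ± 10.7 to 83.8 ± 4.08 CPM, and the synaptic vesicle gene rab-3 from 71.1 to 30.2 CPM. The marker gene unc-119 (M142.1, chromosome III, 10902549 to 10908831) fell from 18.1 ± 1.59 to 12.4 ± 0.81 CPM. The largest falls were in tsp-7, a tetraspanin gene in a locus of 2 genes, and asp-13, an aspartyl protease gene. The level of tsp-7 (T23D8.2) went from 16 ± 2.59 CPM to 0, at least 261-fold lower with a floor of 3 fragments over the group. That of asp-13 (F28A12.4) went from 292 ± 60.5 to 26.3 ± 6.77 CPM, a log2 fold change of −3.47. The yolk protein gene vit-2 was at 0 before heat shock and at least 243-fold higher after it, but at least 19-fold without replicate 3, with 11, 16 and 434 fragments in replicates 1 to 3. Its adjusted p was 0.0018 and ranged from 2e-06 to 0.12 over the alternatives. In all 5457 genes were called with edgeR, 2642 up and 2815 down. With the composition scaling 29.8% of the called genes rose, against 48.4% with TMM.

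**Figure D1:**
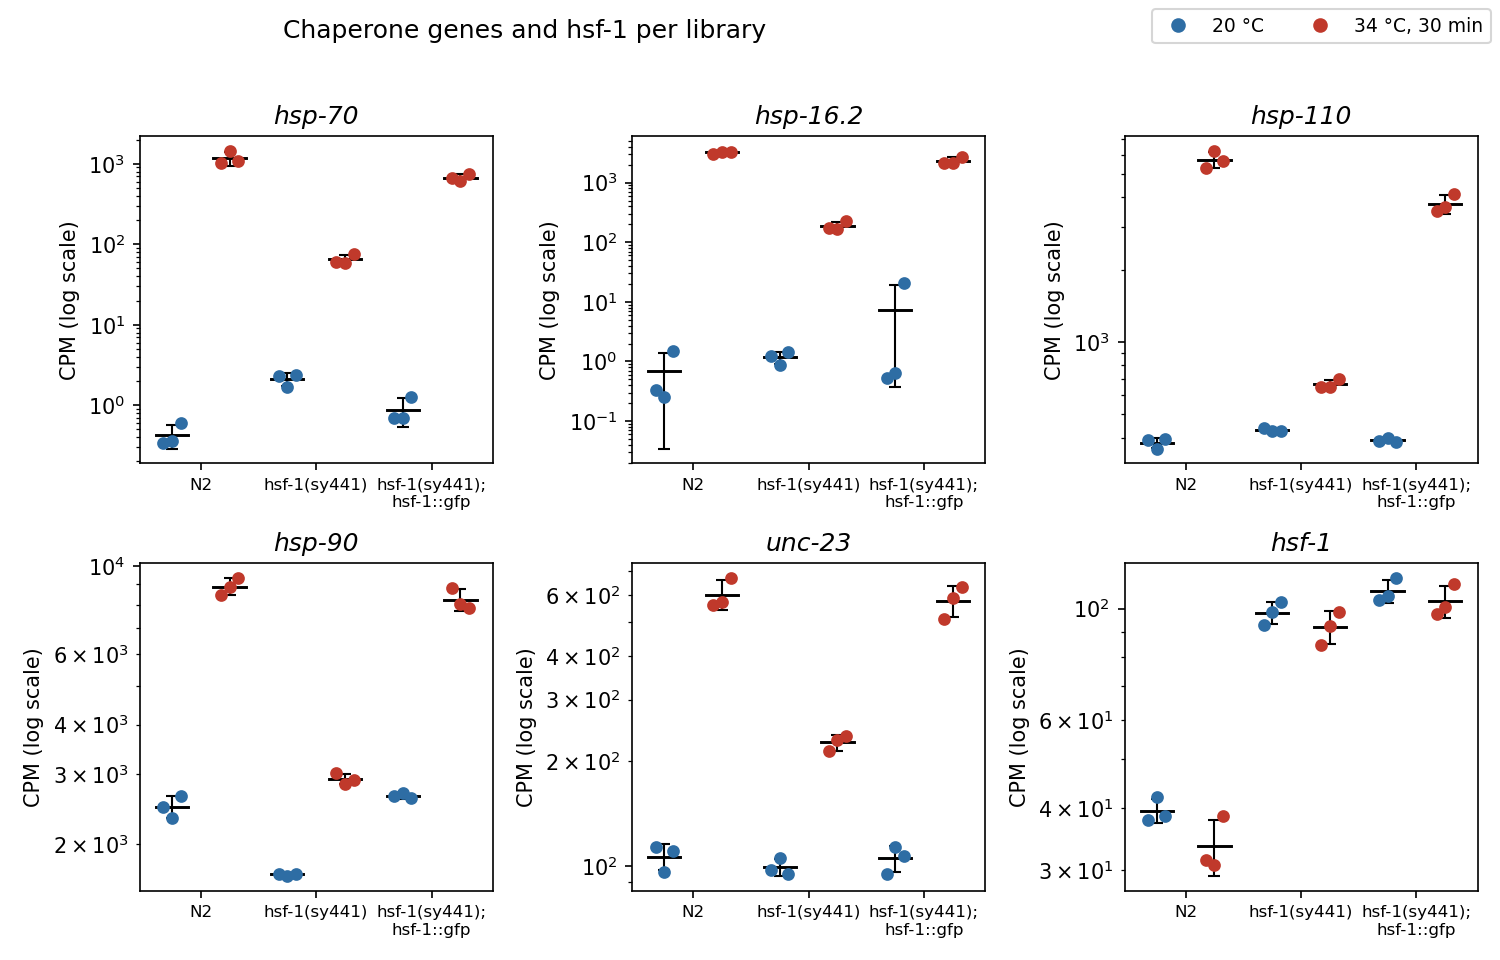
Levels of 5 chaperone genes and hsf-1 in CPM on log axes, by strain and temperature, where points are libraries and bars are means with SD, n = 3. Lower error bars that would reach 0 were shortened on the log axis, and hsp-70 reached 1170 CPM in N2, 64.7 CPM in hsf-1(sy441) and 674 CPM in the transgene strain at 34 °C.

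The same heat shock was given to hsf-1(sy441) larvae. Their hsf-1 level was 98 ± 4.93 CPM before and 91.9 ± 6.95 CPM after heat shock (log2 fold change −0.09, adjusted p = 0.49). The level of hsp-70 rose 30.3-fold, from 2.13 ± 0.391 to 64.7 ± 8.85 CPM. The levels of hsp-16.2 and hsp-16.41 went from 1.19 ± 0.277 to 188 ± 31.3 CPM and from 1.91 ± 0.159 to 236 ± 60.7 CPM. All 4 measured inducible genes rose, and hsp-16.48, at 0 before, was at least 9-fold higher, or at least 5-fold without replicate 3. This gene, uncertain as above, had 1, 8 and 14 fragments at 34 °C. The cuticle collagen gene dpy-17 (F54D8.1) rose 200-fold, from 0.556 ± 0.0641 to 112 ± 36.3 CPM, and asp-13 went from 206 ± 15.9 to 24 ± 3.88 CPM. The difference for unc-119, from 19.4 ± 0.504 to 16.9 ± 2.88 CPM, was not called (adjusted p = 0.25).

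Of the 17 constitutive chaperone genes 8 rose and 0 fell in hsf-1(sy441), over all genes and adjusted over the list alone (median log2 fold change 0.26, adjusted p = 0.014, and adjusted p = 0.58 with an estimated correlation). Their median was 0.02 with the composition scaling, where 4 rose and 2 fell. The level of hsp-90 rose from 1680 ± 11.5 to 2920 ± 89 CPM and that of hsp-110 from 431 ± 5.63 to 665 ± 28.1 CPM. The level of unc-23 rose from 99.1 ± 5.4 to 226 ± 11.7 CPM, while dnj-13, chosen here after its values were seen, had 170 and 160 CPM (adjusted p = 0.65). All 73 ribosomal protein genes rose, by both adjustments, with a median of 0.90 (adjusted p = 1.4e-44, and adjusted p = 0.035 with an estimated correlation). The composition scaling called 71 of these 73. Of the neuron markers 16 fell and 3 rose, 18 and 3 adjusted over the list alone (adjusted p = 8.8e-06, and adjusted p = 0.53 with an estimated correlation). For example, rab-3 went from 83.4 to 36.1 CPM. With edgeR 4493 genes were called, 2247 up and 2246 down, and 19.5% of the called genes rose with the composition scaling against 50% with TMM.

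In the transgene strain heat shock left hsf-1 at 103 ± 7.66 CPM, against 108 ± 5.63 CPM before (log2 fold change −0.07, adjusted p = 0.64). Counts of hsf-1 in this strain, here and below, may hold reads of the endogenous gene and of the transgene, which were not told apart. The level of hsp-70 rose 755-fold, from 0.884 ± 0.344 to 674 ± 65.7 CPM, and R11A5.3 went from 0.393 to 213 ± 33.3 CPM. The level of hsp-16.2 went from 7.38 ± 11.8 to 2330 ± 322 CPM and that of hsp-16.41 from 16.7 ± 28.4 to 2350 ± 311 CPM, with most of the fragments at 20 °C in replicate 3. Their log2 fold changes of 8.30 and 7.13 became 11.97 and 12.91 without it. The call of hsp-16.41 (adjusted p = 1.6e-03) had p-values from 1.6e-08 to 0.061 over the alternatives. All 4 measured inducible genes rose, and hsp-16.48, uncertain as above, was at least 18-fold higher, with 17, 13 and 15 fragments at 34 °C. The marker unc-119 went from 2.96 ± 0.407 to 2.27 ± 0.166 CPM, a fall at an adjusted p of 4.9e-02 that was lost in 14 alternatives, over which p ranged from 0.011 to 0.33.

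Constitutive chaperone genes of the transgene strain had 8 of 17 members up and 1 down, 10 and 1 adjusted over the list alone (median 0.31, adjusted p = 3.6e-08, and adjusted p = 0.062 with an estimated correlation). Of these, hsp-110 rose 9.63-fold, from 389 ± 7.99 to 3750 ± 338 CPM, and hsp-90 rose 3.11-fold, from 2650 ± 38.8 to 8230 ± 503 CPM. The levels of dnj-13 and unc-23 rose from 220 ± 17.9 to 823 ± 77.5 CPM and from 105 ± 9.28 to 576 ± 59.7 CPM. Of the ribosomal protein genes 68 rose, 70 adjusted over the list alone (adjusted p = 2e-29, and adjusted p = 0.062 with an estimated correlation). Neuron markers had 23 members down and 2 up, 24 and 3 adjusted over the list alone (adjusted p = 4.8e-09, and adjusted p = 0.18 with an estimated correlation). The largest falls were again in tsp-7, from 16 ± 4.58 CPM to 0, at least 311-fold, and in K06A4.7 and asp-13, the last from 273 ± 40.8 to 24 ± 3.42 CPM. With edgeR 4854 genes were called, 2272 up and 2582 down, and 24.7% of the called genes rose with the composition scaling against 46.8% with TMM. In all 3 strains 1423 genes rose and 1746 fell, where independent calls would share 66.7 and 80.7.

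Interaction terms tested whether the heat shock response differed between strains. For hsf-1 the response of hsf-1(sy441) differed from that of N2 by a log2 value of 0.14 (adjusted p = 0.79) and from that of the transgene strain by −0.03 (adjusted p = 1.0). The response of hsp-70 in hsf-1(sy441) was smaller than in N2 by −6.49 (SE 0.35, adjusted p = 6.0e-08) and than in the transgene strain by −4.64 (SE 0.33, adjusted p = 2.7e-06). The gene scp-1 (D2013.8), which encodes a relative of the SREBP cleavage-activating protein, went from 55.2 ± 3.5 to 1380 ± 97.4 CPM in N2, from 56.4 ± 0.911 to 93.5 ± 3.59 CPM in hsf-1(sy441) and from 54.5 ± 2.06 to 896 ± 67.9 CPM in the transgene strain. Its differences were −3.91 (adjusted p = 2.4e-11) and −3.31 (adjusted p = 2.3e-10). R11A5.3 differed by −4.26 and −3.08.

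Constitutive chaperones had 5 members with a smaller and 0 with a larger response in hsf-1(sy441) than in N2, 6 and 1 adjusted over the list alone (median −0.14, adjusted p = 8.2e-13, and 0.016 with an estimated correlation). Against the transgene strain 5 members had a smaller and 0 a larger response by both adjustments (median −0.13, adjusted p = 4.6e-18, and 0.0038 with an estimated correlation). Among them hsp-110 differed by −3.28 and −2.64, dnj-13 by −2.24 and −1.99, unc-23 by −1.31 and −1.26, and hsp-90 by −1.04 and −0.84. The endoplasmic reticulum gene hsp-4, chosen after its values were seen, differed by −2.36 (SE 0.28, adjusted p = 4.7e-04) and −1.86 (adjusted p = 7.2e-03). Its level in hsf-1(sy441) went from 140 ± 22.6 to 221 ± 33.8 CPM. The differences of hsp-16.2, also chosen after its values were seen, were −4.94 (SE 1.47, adjusted p = 0.19) and −1.0 (adjusted p = 1.0), so they were not called. The first was −6.1 (adjusted p = 0.14) without replicate 3 of N2 at 20 °C. The second rested on replicate 3 of the transgene strain at 20 °C, with 21 CPM against 0.527 and 0.643 CPM in the other 2 libraries, and was −4.70 (adjusted p = 0.0045) without it. The model took the spread of a gene from all 18 libraries, so that library also entered the SE of the first difference. The first was not examined in a fit without it, so its missing call does not show equal responses in hsf-1(sy441) and N2.

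Against N2 27 genes had a larger response in hsf-1(sy441). The linker histone gene his-24 went from 121 ± 51.3 to 60.9 ± 14.9 CPM in N2 and from 80.8 ± 10.3 to 253 ± 2.4 CPM in hsf-1(sy441), a difference of 2.64 (adjusted p = 1.6e-02). Without replicate 1 of N2 at 20 °C or 34 °C the adjusted p of his-24 was 5.7e-02 or 5.4e-02, and without replicate 1 or 3 of hsf-1(sy441) at 20 °C it was 6.8e-02 or 7.1e-02, in a range from 2.6e-07 to 0.099 over the alternatives. The collagen gene dpy-17 differed by 2.58 (adjusted p = 9.5e-03, range 5.6e-07 to 0.055), and its p was 5.5e-02 without replicate 3 of hsf-1(sy441) at 20 °C. This gene was also called between these strains at 20 °C (adjusted p = 5.2e-04), so a difference before heat shock enters its interaction term. Against the transgene strain 2 genes had a larger response, rgs-6, a regulator of G protein signalling, by 0.72 and Y17G7B.21 by 0.62. Their adjusted p-values were 1.6e-02 and 7.3e-03 and reached 0.23 and 0.086 over the alternatives. The level of rgs-6 went from 32.3 to 30.2 CPM in hsf-1(sy441) and from 31.2 to 17.8 CPM in the transgene strain.

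Between hsf-1(sy441) and N2 edgeR called 70 interactions, 27 larger and 43 smaller in the mutant. This fit had no block, although libraries of the same replicate number resembled each other between temperatures. Their deviations from the group mean had correlations across genes of 0.37 to 0.79 in N2 and 0.18 to 0.72 in hsf-1(sy441). The balance differed between fits, with 454 genes (333 larger, 121 smaller) with replicates as a block, 397 (236 and 161) with DESeq2, 230 (135 and 95) with the score described below, 57 (17 and 40) with the composition scaling and 54 (6 and 48) with limma on log2(FPKM + 0.1). Without replicate 1 or 2 of N2 at 20 °C the count was 42 or 40, without replicate 1 or 3 of hsf-1(sy441) at 20 °C it was 39 or 40, and without replicate 3 of N2 at 34 °C it was 161. Against the transgene strain 28 were called, 2 larger and 26 smaller, 61 (26 and 35) with the block, 69 (16 and 53) with DESeq2 and 48 (11 and 37) with the score. Between the transgene strain and N2 edgeR called 0 genes, while DESeq2 called 13 and limma 0. Of the 14219 genes 610 had an unadjusted p under 0.05 with edgeR, a share below the 0.05 that unchanged genes alone would give. Without replicate 2 of N2 at 34 °C 1 gene was called. There hsp-70 and hsp-110 were chosen after their values were seen, and hsp-70 differed by −1.85 (SE 0.36, adjusted p = 0.54) and hsp-110 by −0.64 (adjusted p = 0.35).

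The next question was which transcripts differed between hsf-1(sy441) and N2 larvae at 20 °C. The level of hsf-1 was 2.48-fold higher in hsf-1(sy441), 98 ± 4.93 against 39.5 ± 2.17 CPM (log2 fold change 1.31, SE 0.09, adjusted p = 4.1e-07). It lay in a run of 28 neighbouring genes on chromosome I, of which 25 were called higher in hsf-1(sy441) and 20 in the transgene strain than in N2. The kinase gene wee-1.1 (F35H8.7) was 79.2-fold higher, 10.6 ± 2.78 against 0.142 ± 0.177 CPM, a log2 fold change of 6.31 that was 7.91 without replicate 3 of N2, and C38D9.2 was 61-fold higher, 17.3 ± 1.72 against 0.274 ± 0.0807 CPM. The level of hsp-70, chosen here after its values were seen, was 2.13 ± 0.391 against 0.431 ± 0.142 CPM, a log2 fold change of 2.32 (SE 0.27, adjusted p = 9.1e-05). Among the constitutive chaperones 4 of 17 were lower and 0 higher, over all genes and adjusted over the list alone (median −0.17, adjusted p = 0.018, and adjusted p = 0.43 with an estimated correlation). With the composition scaling this median turned to 0.04, with 3 higher and 2 lower. The level of hsp-90 was 1.48-fold lower, and that of the Hsp90 co-chaperone gene fkb-6, in a locus of 2 genes, was lower with a log2 fold change of −0.66 (adjusted p = 3.8e-04).

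**Figure D2:**
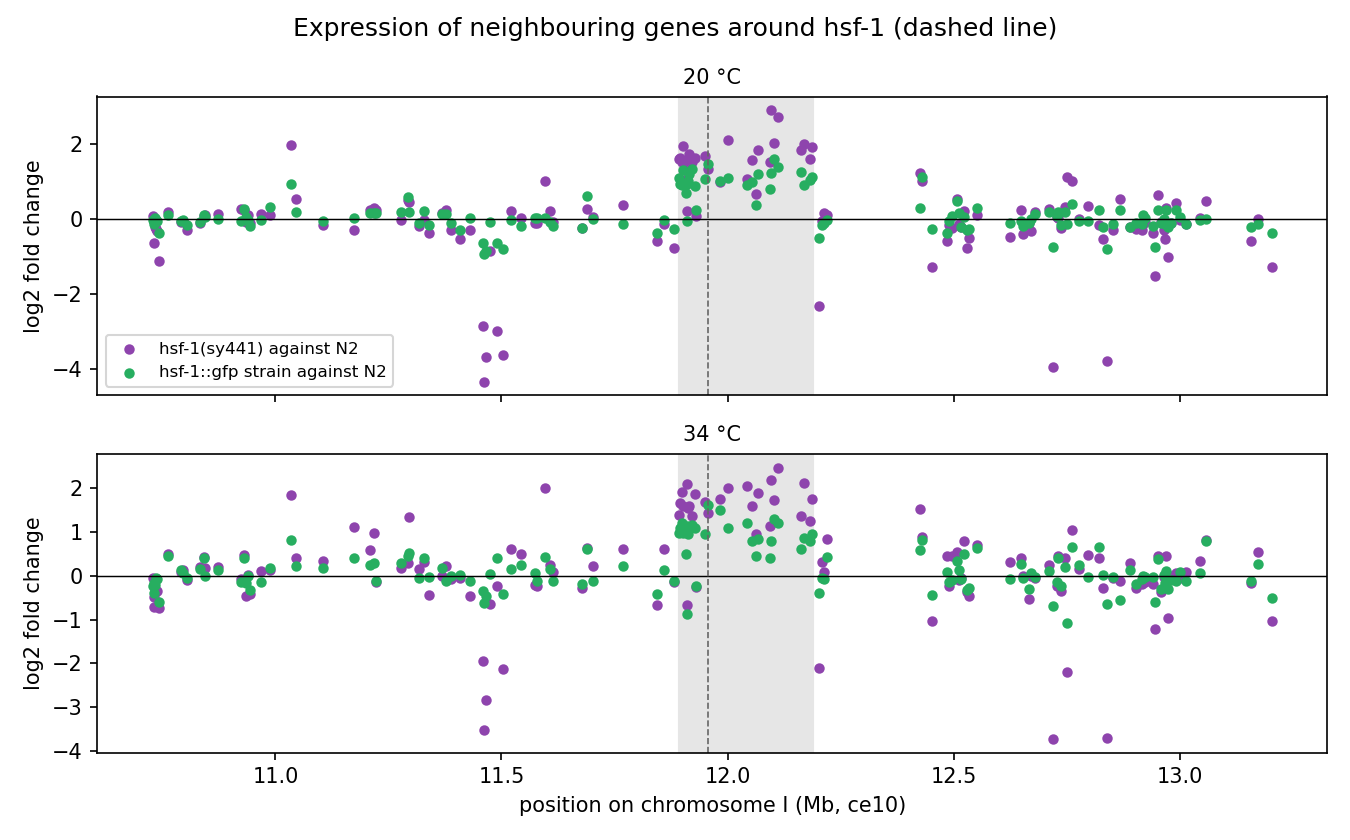
Log2 fold changes of genes against their position on chromosome I (Mb, ce10) at 20 °C and 34 °C, where points are genes in hsf-1(sy441) or the transgene strain against N2, from 3 libraries a group, with no error bars. The grey band marks the run of 28 genes with hsf-1 (dashed line), where medians at 20 °C were 1.60 and 1.03.

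Of the lists described at 20 °C, 43 genes of cuticle and moulting, measured as part of larval development, had the largest median difference. Of these 23 were lower and 1 higher in hsf-1(sy441), 34 and 1 adjusted over the list alone, with a median of −1.94 (adjusted p = 5.7e-09, and adjusted p = 0.43 with an estimated correlation). The hedgehog-related gene grl-7 had 9.48 ± 4.06 against 360 ± 306 CPM, and the collagen gene dpy-13 had 52.7 ± 25.5 against 1340 ± 1110 CPM. Their log2 fold changes of −5.25 and −4.66 were −4.48 and −3.97 without replicate 2 of N2. The call of grl-7 (adjusted p = 2.0e-02) had p-values up to 0.095 over the alternatives and was lost without any of 5 of the 6 libraries, replicate 3 of N2 excepted. That of dpy-13 (adjusted p = 1.7e-02) had p-values from 4.7e-05 to 0.11, with 6.0e-02 without replicate 2 of N2 and 6.6e-02 and 8.4e-02 without replicates 2 and 3 of hsf-1(sy441). Libraries of 1 group differed in the same genes, since 57.3% of the variance within groups lay on 1 axis, and 23 of the 43 cuticle genes were in its top 5% of loadings. All libraries of hsf-1(sy441) at 20 °C lay below every N2 library on this axis. The correlation across genes, which are not independent replicates, between the log2 fold change and the loading was −0.78. Other splits of these libraries, centred within groups so that no strain effect was left, gave correlations of a size up to 0.90. With the score on this axis as a covariate, chosen after seeing the data, 4 cuticle genes were lower and the median was −0.62. The list as a whole kept its call in that fit. Since the score itself parted hsf-1(sy441) from N2, the covariate also takes up strain difference along the axis. Calls lost with the score, here and below, therefore do not tell a strain effect from differences between replicates.

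Proteasome, replication and energy genes were also lower in hsf-1(sy441) at 20 °C. Of 30 proteasome genes 15 were lower, all 30 adjusted over the list alone, 4 with the composition scaling and 0 with the score, where the list's adjusted p was 0.067 (median −0.56, adjusted p = 5.7e-09, and adjusted p = 0.46 with an estimated correlation). Of 53 genes of DNA replication and the cell cycle 21 were lower and 2 higher, 31 and 3 adjusted over the list alone, 12 and 6 with the composition scaling, and 3 and 0 with the score (adjusted p = 1.1e-06, and adjusted p = 0.43 with an estimated correlation). The replicative helicase gene mcm-7 had 34.6 against 53.8 CPM. Of 38 respiratory chain and ATP synthase genes 18 were lower, 25 adjusted over the list alone, 4 with the score and 1 with the composition scaling (adjusted p = 5e-06, and adjusted p = 0.43 with an estimated correlation). Of the 19 endoplasmic reticulum genes 9 were lower, 11 adjusted over the list alone and 3 with the composition scaling (adjusted p = 5.3e-05, and adjusted p = 0.43 with an estimated correlation). The DnaJ gene dnj-7 had 108 against 168 CPM.

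Ribosome biogenesis genes were higher in hsf-1(sy441), 17 of 25, or 20 adjusted over the list alone (median 0.30, adjusted p = 6.7e-06, and adjusted p = 0.43 with an estimated correlation). Of these, nol-16 had 85.4 ± 4.28 against 59.3 ± 1.07 CPM and pro-2 had 188 ± 9.1 against 138 ± 2.84 CPM. Of 20 genes of the intracellular pathogen response 6 were higher by both adjustments, and 0 with the score, where the list's adjusted p was 0.42 (adjusted p = 0.017, and adjusted p = 0.46 with an estimated correlation). With edgeR 2969 genes were called, 1340 higher and 1629 lower, and 1319 with the score. With the composition scaling 77.5% of the called genes were higher, against 45.1% with TMM. The count was 1057 and 991 without replicate 1 or 2 of N2 and 1743, 1242 and 889 without replicates 1, 2 and 3 of hsf-1(sy441). Of 45 genes named by the rule and called, 32 lost the call in at least 1 of the alternatives compared, so examples given here were mostly those that kept it.

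**Figure D3:**
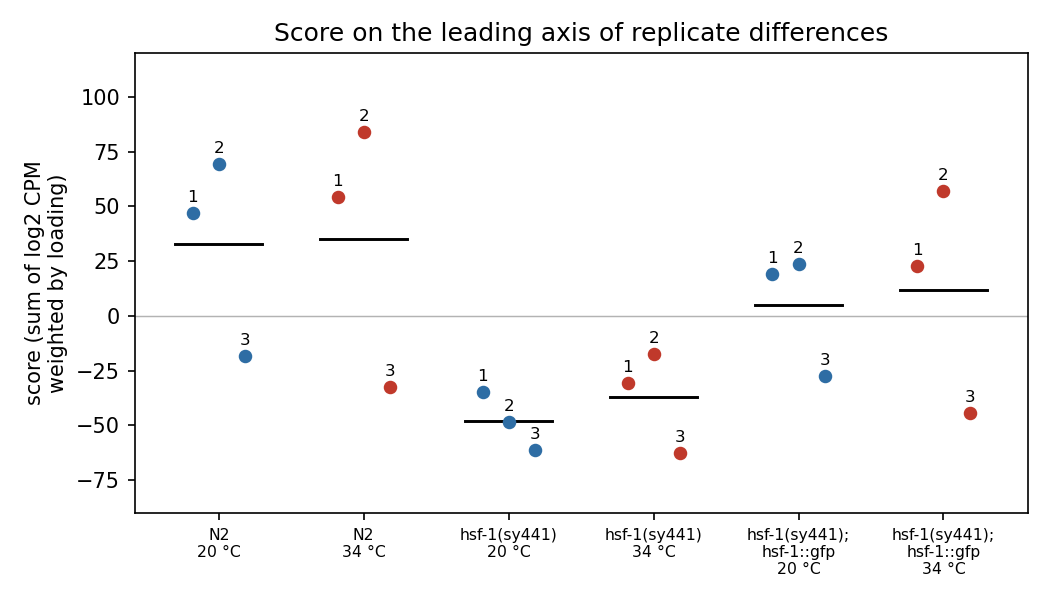
Score of each library on the leading axis of replicate differences (sum of log2 CPM weighted by loading), by strain and temperature, where points with numbers are replicates and lines are group means, n = 3, with no error bars. Replicate 3 was lowest in each group, and all hsf-1(sy441) libraries at 20 °C lay below every N2 library.

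Comparing hsf-1(sy441) with the transgene strain at 20 °C asked which of these differences were also found between these 2 strains. Besides the transgene, they differed in unc-119(ed9), in the aqp-10 level given below and in the run of 28 genes on chromosome I. That run had a median log2 fold change of 0.6 in hsf-1(sy441) against the transgene strain, with 14 of its 28 genes called higher. A difference between these strains, here and in heat shock, therefore cannot be assigned to the transgene alone. The hsf-1 levels of 98 ± 4.93 and 108 ± 5.63 CPM gave a log2 fold change of −0.14 (adjusted p = 0.39), which does not compare the endogenous gene alone. The level of hsp-90 was 1.57-fold lower in hsf-1(sy441), 1680 ± 11.5 against 2650 ± 38.8 CPM, and that of fkb-6 was 115 against 174 CPM. Constitutive chaperones had 4 of 17 lower, 7 adjusted over the list alone and 2 without replicate 3 of the transgene strain (median −0.22, adjusted p = 0.00068, and adjusted p = 0.52 with an estimated correlation). Of the 13 chaperonin and prefoldin genes 3 were lower, 6 adjusted over the list alone (adjusted p = 0.0051, and adjusted p = 0.52 with an estimated correlation), with cct-3 at 381 ± 15.6 against 518 ± 26.7 CPM. The aquaporin gene aqp-10 (ZK1321.3, chromosome II, 9768392 to 9769793) had 88.4 ± 4.18 CPM against 0.0605 ± 0.0647 CPM in the transgene strain, a log2 fold change of 10.35 that was 11.53 without replicate 2 of the latter. The level of wee-1.1 was 47.6-fold higher and that of unc-119, the gene mutated by ed9 in the transgene strain, 6.55-fold higher, 19.4 ± 0.504 against 2.96 ± 0.407 CPM. The gene rop-1, which encodes the Ro RNA-binding protein and shares its locus, had 32.5 ± 3.16 against 161 ± 7.44 CPM.

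Cuticle and moulting genes had a median of −1.24 with 0 called by edgeR, also adjusted over the list alone (adjusted p = 4.7e-08, and adjusted p = 0.52 with an estimated correlation). Of these genes 22 were lower at an unadjusted p under 0.05, 12 by DESeq2, 0 by limma and 5 with the score, and fry's adjusted p was 0.071. Proteasome genes had a median of −0.36 with 0 called by edgeR by both adjustments, 10 lower at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma. Their adjusted p was 1.6e-06 with camera, with adjusted p = 0.52 with an estimated correlation, 0.11 with fry and 0.26 with the score. In all 659 genes were called, 363 higher and 296 lower in hsf-1(sy441), and 79.7% of the called genes were higher with the composition scaling against 55.1% with TMM. The count was between 348 and 428 without each of replicates 1, 2 and 3 of hsf-1(sy441), and 390 and 333 without replicates 1 and 2 of the transgene strain. DESeq2 called 1523. Of the genes called against N2, 303 were also higher and 195 also lower against the transgene strain, where independent calls would share 34.2 and 33.9. Both comparisons use the same hsf-1(sy441) libraries, and part of the excess may come from these. In 20 simulations of unchanged groups, which drew genes independently and so lacked the axis above, the mean overlap was 0.1 genes and the mean covariance of log2 fold changes 0.057, against 498 and 0.594 observed. The correlation across genes, which are not independent replicates, of the 2 differences in mean log2 CPM was 0.86. The same libraries, centred within groups and put into 756 other groupings that kept no group whole, gave a median of 0.56 and up to 0.95, so this correlation does not set a strain effect apart from differences between replicates.

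The transgene strain was compared with N2 at 20 °C to see what it did not share with the wild type. Its hsf-1 level, with reads of gene and transgene not told apart, was 2.74-fold higher (log2 fold change 1.46, adjusted p = 3.9e-07). The level of unc-119 was 6.11-fold lower, and that of aqp-10 was 0.0605 ± 0.0647 against 102 ± 5.01 CPM, 1520-fold lower, with a log2 fold change of −10.57 that was −11.74 without replicate 2 of the transgene strain. C38D9.2 was 51.9-fold higher, 14.7 ± 3.5 against 0.274 CPM, and F33H2.6 was 11.8-fold higher, 47.3 ± 3.89 against 4.01 ± 0.356 CPM. The pump gene catp-3 had 39 ± 8.02 against 6.67 ± 1.76 CPM, and the venom allergen-like gene vap-1 had 16.7 ± 2.68 against 64.6 ± 9.95 CPM. Of the chaperones, chosen after their values were seen, hsp-110 had a log2 fold change of 0.03 (adjusted p = 0.89), hsp-90 one of 0.09 (adjusted p = 0.65) and hsp-70 one of 1.06 (adjusted p = 0.14).

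Germline markers had 1 of 38 genes lower, 5 adjusted over the list alone (median −0.20, adjusted p = 1.7e-05, adjusted p = 0.89 with an estimated correlation, fry 0.23). That gene, pgl-1, a component of germ granules, had 54.7 against 83 CPM with an adjusted p of 3.9e-02 and a range of 0.00038 to 0.28 over the alternatives. Cuticle and moulting genes had a median of −0.58 with 0 called by edgeR, also adjusted over the list alone, 1 lower at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma (adjusted p = 0.005, and adjusted p = 0.89 with an estimated correlation). Their adjusted p was 0.69 with fry and 0.40 without replicate 3 of the transgene strain, and with the score the median turned to 0.05 (adjusted p = 0.98). In all 189 genes were called, 135 higher and 54 lower, 668 with replicates as a block and 450 with DESeq2. The count was 101 or 117 without replicate 1 or 2 of N2 and 118 without replicate 3 of the transgene strain, and 83.3% of the called genes were higher with the composition scaling against 71.4% with TMM.

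At 34 °C the levels after heat shock were compared between strains. The level of hsf-1 was 2.74-fold higher in hsf-1(sy441) than in N2 (log2 fold change 1.45, adjusted p = 9.7e-08). The level of hsp-110 was 8.62-fold lower, 665 ± 28.1 against 5730 ± 450 CPM, that of dnj-13 7.06-fold lower, 160 ± 3.71 against 1130 ± 113 CPM, and that of hsp-90 3.04-fold lower. Constitutive chaperones had 11 of 17 genes lower and 1 higher, 12 and 1 adjusted over the list alone, 7 and 1 with the composition scaling and 8 and 2 with the score (median −0.32, adjusted p = 8.7e-11, and 0.035 with an estimated correlation). For hsp-70, chosen here after its values were seen, the log2 fold change was −4.18 (SE 0.23, adjusted p = 1.8e-08). The level of wee-1.1 was 14.2 ± 3.71 CPM, 31.9-fold higher, and that of epic-2, an embryonic P granule gene, 161 ± 23 against 7.89 ± 6.6 CPM. Their log2 fold changes of 4.99 and 4.36 were 5.70 and 5.21 without replicate 3 of N2. The level of unc-119 was higher by 0.45 with edgeR (adjusted p = 1.7e-02). Over the alternatives its adjusted p ranged from 0.0061 to 0.12, and it was 5.7e-02 without replicate 2 of N2 and 7.8e-02 without replicate 1 of hsf-1(sy441).

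Proteasome genes had 23 of 30 lower in hsf-1(sy441) at 34 °C, 26 adjusted over the list alone and 5 with the score (median −0.57, adjusted p = 2.3e-08, and adjusted p = 0.53 with an estimated correlation). The proteasome lid gene rpn-3 had 242 ± 30.5 against 577 ± 70.4 CPM. Of 64 mitochondrial ribosomal protein genes 39 were lower, 46 lower and 1 higher adjusted over the list alone, 22 lower and 2 higher with the composition scaling, and 24 and 2 with the score (adjusted p = 1.7e-09, and adjusted p = 0.53 with an estimated correlation). Of 37 glutathione S-transferase and oxidative response genes 15 were lower and 3 higher by both adjustments (adjusted p = 0.00029, and adjusted p = 0.079 with an estimated correlation), with gst-4 at 26.7 ± 0.517 against 51.5 ± 7.74 CPM. In all 4124 genes were called, 2111 higher and 2013 lower, and 884 with the compared groups alone. The count was 2331 or 2619 without replicate 1 or 2 of N2 and 2456 without replicate 3 of hsf-1(sy441), and 68.8% of the called genes were higher with the composition scaling against 51.2% with TMM.

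Against the transgene strain at 34 °C hsf-1 had a log2 fold change of −0.17 in hsf-1(sy441) (adjusted p = 0.26). The level of hsp-70 was 10.4-fold lower, 64.7 ± 8.85 against 674 ± 65.7 CPM, that of hsp-110 5.63-fold, that of dnj-13 5.13-fold and that of hsp-90 2.82-fold lower. Constitutive chaperones had 10 of 17 genes lower, 12 adjusted over the list alone (median −0.45, adjusted p = 6.7e-18, and 0.0038 with an estimated correlation). The level of hsp-16.2 was 12.4-fold lower, 188 ± 31.3 against 2330 ± 322 CPM (adjusted p = 3.3e-02). Its adjusted p was between 6.7e-02 and 0.11 without any 1 library except replicate 3 of the transgene strain, and between 0.0004 and 0.11 over all alternatives. The levels of aqp-10 and unc-119 were at least 1942-fold and 7.46-fold higher, and K09C6.9 had 18.8 ± 1.03 against 2.28 ± 0.666 CPM. Of 32 neuron markers, which include unc-119, 12 were higher, 15 adjusted over the list alone (median 0.24, adjusted p = 1.3e-06, and adjusted p = 0.34 with an estimated correlation). With edgeR 1299 genes were called, 745 higher and 554 lower, 3140 with replicates as a block, 265 with the compared groups alone and 2239 with DESeq2. It was 777 and 755 without replicates 1 and 3 of hsf-1(sy441) and 695 and 619 without replicates 1 and 2 of the transgene strain, and 67.8% of the called genes were higher with the composition scaling against 57.4% with TMM.

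Between the transgene strain and N2 at 34 °C hsf-1 was 3.08-fold higher (log2 fold change 1.62, adjusted p = 1.1e-07). F32B5.1 had 10.4 ± 1.46 against 0.237 CPM, 44.6-fold higher (log2 fold change 5.48, and 6.4 without replicate 3 of N2), and catp-3 had 51.4 ± 9.13 against 6.4 ± 2.04 CPM. The level of aqp-10 was at least 2544-fold lower and that of unc-119 5.46-fold lower. Several heat shock genes, chosen after their values were seen, were lower in the transgene strain, with log2 fold changes of −0.61 for hsp-110 (adjusted p = 2.9e-04), −0.62 for scp-1 (adjusted p = 2.8e-04), −0.46 for dnj-13 (adjusted p = 4.7e-02) and −1.14 for R11A5.3 (adjusted p = 2.0e-02). The adjusted p of dnj-13 was between 0.065 and 0.14 without any 1 library except replicate 3 of N2. That of R11A5.3 was between 0.063 and 0.075 without replicate 1 or 2 of N2 or replicate 1 or 3 of the transgene strain. For hsp-70 the log2 fold change was −0.80 (SE 0.20, adjusted p = 5.1e-02, and 0.037 without replicate 3 of N2) and for hsp-90 −0.11 (adjusted p = 0.40). Mitochondrial ribosomal protein genes had 1 of 64 higher and 1 lower, 1 and 16 adjusted over the list alone (median −0.18, adjusted p = 8.6e-06, adjusted p = 0.97 with an estimated correlation, fry 0.27).

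In this comparison 386 genes were called, 231 higher and 155 lower, 1338 with replicates as a block, 22 with the compared groups alone and 924 with DESeq2. Without replicate 1 or 3 of N2 the count was 164 or 887, and without replicates 1, 2 and 3 of the transgene strain it was 231, 225 and 251. With the composition scaling 77.4% of the called genes were higher against 59.8% with TMM.

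The authors' deposited tests were compared with these calls. Their table of heat shock in N2 held 1684 genes, 950 up and 734 down. Of those tested here 88.3% were also called in the same direction. At 20 °C the authors' tables marked 2684 genes for hsf-1(sy441) against N2, of which 59.7% of those tested were also called in the same direction, 1665 against the transgene strain (21.7%) and 962 for the transgene strain against N2 (12.5%). At 34 °C they marked 1760 (65.2%), 922 (34.4%) and 363 (29.9%). For hsp-70 in N2 the authors' log2 ratio was 11.54, against 11.41 here. The authors' table marked hsp-16.41 in the transgene strain against N2 at 20 °C, with a log2 ratio of 4.89 and a q value of 0.00078, where edgeR gave 4.96 with an adjusted p of 0.15. This value rested on replicate 3 of the transgene strain, with 49.5 CPM against 0.264 and 0.343 CPM in the other 2 libraries, and turned to −0.79 (adjusted p = 0.89) without it. It was 5.82 (adjusted p = 0.21) without replicate 3 of N2.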

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

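The tests of the strain differences at 20 °C and of hsp-16 at 20 °C, the splits for comparisons of 2 groups and those of the interactions that keep pairs were chosen only after the result was seen, while the interaction tests, the fits without 1 library and the other splits of the 3 interactions were planned before.

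The heat shock response differed between strains by its interaction terms, for 70 genes between hsf-1(sy441) and N2 and for 28 genes between hsf-1(sy441) and the transgene strain. The terms for hsp-70 were −6.49 and −4.64, those for scp-1 −3.91 and −3.31, and those for R11A5.3 −4.26 and −3.08. The gene srt-42, in the locus merged with hsp-16.2 and hsp-16.41, had −3.65 and −2.87. Among constitutive chaperones hsp-110 had −3.28 and −2.64, dnj-13 −2.24 and −1.99, unc-23 −1.31 and −1.26, and hsp-90 −1.04 and −0.84.

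Larger responses in hsf-1(sy441) than in N2 were called for 2 linker histone genes, his-24 with 2.64 and hil-3 with 1.59, for dpy-17 with 2.58 and for F58G1.7 with 1.86. Without replicate 1 of N2 at 20 °C or 34 °C the adjusted p of his-24 was 5.7e-02 or 5.4e-02, and without replicate 1 or 3 of hsf-1(sy441) at 20 °C it was 6.8e-02 or 7.1e-02. That of dpy-17 was 5.5e-02 without replicate 3 of hsf-1(sy441) at 20 °C. That of hil-3 was between 5.8e-02 and 0.17 without any of 9 libraries, which were all but replicate 3 of N2 at 20 °C and replicates 2 and 3 of N2 at 34 °C. That of F58G1.7 was between 6.2e-02 and 0.17 without any of 10 libraries, all but replicate 3 at 20 °C and replicate 2 at 34 °C of N2.

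Compared with the transgene strain, rgs-6 had 0.72 and Y17G7B.21 had 0.62. The adjusted p of rgs-6 was between 5.2e-02 and 0.11 without any of 7 libraries, namely the 3 of hsf-1(sy441) at 20 °C, its replicate 3 at 34 °C, and replicate 1 at 20 °C and replicates 1 and 2 at 34 °C of the transgene strain. That of Y17G7B.21 was 7.5e-02 and 8.6e-02 without replicates 1 and 3 of hsf-1(sy441) at 20 °C and 6.2e-02 without replicate 3 of the transgene strain at 20 °C.

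For these interactions 33 splits of the libraries were drawn, with fits of the 4 groups compared. Between hsf-1(sy441) and N2, 3 splits, the real one included, gave at least the real 65 genes, so these splits did not exclude chance. Of these, the split with 84 genes exchanged no label at 34 °C and so kept the strain difference there. Other splits that left these labels in place gave 23 to 45 genes. The highest other gave 1504 in a split that exchanged 2 labels of each strain at 34 °C alone. Such a split keeps the strain difference at 20 °C in the contrast, so it is no null for the interaction. The 2 other splits of that kind gave 0 and 2, and why they differed was not tested. Between hsf-1(sy441) and the transgene strain 1 split, the real one, gave 35 genes, and the highest other gave 28. Other splits that kept the 34 °C libraries of each strain together gave 24 to 28 genes, and the rest gave 0. The count thus followed the strain difference at 34 °C, so these splits did not exclude chance for the interaction. Between the transgene strain and N2 all 33 splits gave at least the real 0, and the highest other gave 1. These splits shuffled labels within each temperature and so broke the pairs of replicate numbers.

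Splits that moved pairs whole, with a block for each pair, numbered 10, so that no share under 0.05 can be reached. Every other split mixed pairs of both strains, so a real difference in response would widen the spread within its groups and lower its count. Between hsf-1(sy441) and N2 1 split, the real one, gave 430 genes, and the highest other gave 0. Against the transgene strain 1 split, the real one, gave 62 genes, and the highest other gave 1. Between the transgene strain and N2 all 10 splits gave at least the real 0, and the highest other gave 2.

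Each comparison of 3 libraries with 3 has 10 splits, so that no share under 0.05 can be reached. In all 9 comparisons 1 split, the real one, gave as many genes, and the highest other split gave 0 with fits of the compared groups alone, which was also the highest among the splits that part all pairs of replicate numbers. Every other split mixed libraries of both groups, so real differences widened the spread within its groups and lowered its count. These counts therefore do not decide whether chance played a part. The real splits gave 3597, 5121 and 3509 genes for heat shock in N2, hsf-1(sy441) and the transgene strain. At 20 °C they gave 3535 for hsf-1(sy441) against N2, 1158 against the transgene strain and 81 for the transgene strain against N2, and at 34 °C 884, 265 and 22.

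The differences between strains at 20 °C followed the axis on which replicates of 1 group differ, with correlations across genes of −0.78 for hsf-1(sy441) against N2, −0.66 against the transgene strain and −0.54 for the transgene strain against N2. At 34 °C these were −0.71, −0.64 and −0.41, and heat shock gave 0.01, 0.13 and 0.10, but other splits of centred libraries gave sizes up to 0.90 for hsf-1(sy441) against N2 at 20 °C, so the correlation decides nothing. The median of the cuticle and moulting list stayed at −1.73 with the shift between scalings added, which argues against these scalings as the whole cause of its lower level. This sum of known values is no test of the axis, since 1 shift for all genes cannot make or remove it. A candidate explanation is that libraries differed in the phase of the second larval stage, which the 53.5% of cuticle and moulting genes in the top 5% of its loadings go with. Whether sy441 sets that phase or the time of harvest did cannot be told apart, because both predict that the 3 libraries of hsf-1(sy441) lie below every N2 library, as they did, and no library of a timed series was measured.

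In replicate 3 of the transgene strain at 20 °C hsp-16.41 had 49.5 CPM from 1081 fragments and hsp-16.2 had 21 CPM from 458 fragments, against means of 0.303 and 0.585 CPM in the other 2 libraries. RNA or reads from libraries of the transgene strain at 34 °C would need a share of 2.09% or 0.875% for these genes, at least 0.634% if from N2 or 10.9% if from hsf-1(sy441), and would raise all other induced genes too. Over 8 other genes over 32-fold up in heat shock the median implied share was −0.00414% with an SD of 0.539, and −0.0102% (SD 0.623) and −0.0906% (SD 1.78) with the other 2 groups as the source, which argues against all 3. Y43F8B.2 alone implied 1.21%, 7 genes implied less than 0.5 times 0.875%, and hsp-70 had 28 fragments where that share would bring 129. A brief or mild exposure to heat cannot be told apart from other sources, since hsp-70 had 1.28 CPM there against 0.686 CPM, and no sample of graded exposure was measured.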

How the results depend on the processing

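The score as a covariate, and the list tests with the score, with a block or without replicate 3 of the transgene strain at 20 °C, were chosen only after the result was seen, and the other alternatives were planned. The score differed between strains as well as between replicates, so calls lost with it do not tell these apart. Of 278 results for genes in a comparison, 277 kept their direction and side of the threshold with RLE size factors in edgeR, 266 without a filter, 261 with the composition scaling, 273 with a replicate block, 250 with the compared groups alone, 241 with limma on log2 FPKM with a pseudocount of 1 and 252 with the score. With the Wald test of DESeq2 267 of 269 did. Of 1836 results without 1 library, 1621 stayed, 209 lost and 2 gained a call, and 4 reversed. The cause was not tested for any change here, except that stricter thresholds lower counts by construction. Leaving out 1 library lowered some counts and raised others. For the transgene strain against N2 at 34 °C the count went from 386 to 164 without replicate 1 of N2 and to 887 without its replicate 3.

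Reversed results were all of differences not called in the main test except a list. For hsf-1 the interaction between hsf-1(sy441) and the transgene strain was 0.03 without replicate 1 of hsf-1(sy441) at 34 °C, 0 without replicate 1 of the transgene strain at 20 °C and 0.03 without its replicate 3 at 34 °C. Its lowest value without 1 library was −0.13. Its heat shock value in the transgene strain was 0.02 without replicate 3 at 20 °C, and the lowest without 1 library was −0.13. The cuticle and moulting list of the transgene strain against N2 at 20 °C turned with the score, at an adjusted p of 0.98.

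With an absolute log2 fold change of at least 1 heat shock gave 1657 genes in N2, 1307 in hsf-1(sy441) and 1637 in the transgene strain. With an adjusted p under 0.01 heat shock in hsf-1(sy441) gave 2920, and fits of the compared groups alone gave 3597 in N2. Without 1 library counts ran from 4591 to 5485 in N2, from 3413 to 4179 in hsf-1(sy441) and from 3882 to 4805 in the transgene strain.

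For hsf-1(sy441) against N2 at 20 °C the 2 pseudocounts of 1 and 0.1 gave 1567 and 1596 genes, the threshold of 0.01 gave 802, that of log2 1 gave 1274 and the score 1319. The replicate block gave 5034, but replicate numbers paired the libraries there only in part. Deviations from the group mean had correlations across genes of 0.41, −0.06 and 0.22 between the libraries of replicates 1, 2 and 3. Against the transgene strain DESeq2 gave 1523, the pseudocounts 424 and 422, the thresholds 283 and 276, the compared groups 1158 and the score 1012. The block gave 2557, where these correlations were 0.29, 0.05 and 0.53. For the transgene strain against N2 DESeq2 gave 450, the pseudocounts 120 and 122, the thresholds 105 and 90, the compared groups 81, the block 668 and the score 474. Without 1 library these 3 counts ran from 889 to 3409, from 333 to 528 and from 101 to 167.

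At 34 °C the thresholds gave 1692 and 1237 genes for hsf-1(sy441) against N2 and the compared groups 884. Against the transgene strain DESeq2 gave 2239, the pseudocount of 0.1 gave 788, the thresholds 486 and 371, the compared groups 265 and the block 3140. For the transgene strain against N2 DESeq2 gave 924, the pseudocounts 242 and 225, the thresholds 131 and 101, the compared groups 22, the block 1338 and the score 902. Without 1 library they ran from 2331 to 5281, from 619 to 1874 and from 164 to 887.

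For the interaction between hsf-1(sy441) and N2 DESeq2 gave 397 genes, the thresholds 34 and 44, the block 454, the score 230, and leaving out 1 library 39 to 161. Between hsf-1(sy441) and the transgene strain DESeq2 gave 69, the block 61, the score 48 and leaving out 1 library 25 to 34. Between the transgene strain and N2 DESeq2 gave 13 and leaving out 1 library 0 to 1.

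The gene list tests gave 123 calls, 5 with an estimated correlation and 86 with fry, which tests another null. The overlap of both 20 °C comparisons with hsf-1(sy441) went from 498 to 193 genes and that of heat shock in 3 strains from 3169 to 1996 at an adjusted p under 0.01, and the authors' marked genes from 10040 to 6521 at a q value under 0.01. With the block rpn-3 and pas-3 were called at 20 °C against the transgene strain (3.5e-04 and 3.9e-03, with pairs only in part), K02E11.10 was lost at 34 °C against N2 (0.11), hsf-1 in heat shock of N2 was called (2.2e-02) and unc-119 in heat shock of the transgene strain was lost (5.3e-02). With the block the constitutive chaperone list of hsf-1(sy441) against N2 at 20 °C was also lost (0.091, with pairs only in part). The block changed no other call of a gene named by the rule or of a list described. Genes chosen after their values were seen were not checked with it. At this depth the test on simulated data called 162 of 670 genes changed 1.5-fold, all with a mean above 5 CPM. It had 200 changed genes among 14219, so its adjusted threshold was stricter than in heat shock of N2, where 5457 were called. This share does not carry over to comparisons with many called genes, though small differences could still be missed.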

Other observations

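All tests of the hypothesis in this part were chosen only after the result was seen, and the lists were fixed before.

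Further lists moved in heat shock. Of 30 translation factor genes 20 rose and 3 fell in N2, 17 and 0 in hsf-1(sy441), and 18 and 2 in the transgene strain. Adjusted over the list alone these were 20 and 3, 20 and 1, and 21 and 4, and camera's adjusted p-values were 0.00044, 0.00011 and 0.0011, with adjusted p = 0.60, 0.58 and 0.55 with an estimated correlation. Of 19 body wall muscle markers 7 rose and 2 fell in N2, 13 and 0 in hsf-1(sy441), and 11 and 0 in the transgene strain, and adjusted over the list alone 9 and 2, 15 and 0, and 15 and 1. Their adjusted p-values were 0.034, 0.00012 and 0.0014, and 0.81, 0.58 and 0.55 with an estimated correlation. The interaction test of these markers between hsf-1(sy441) and N2 had a median of 0.23 with 0 genes called by edgeR, also adjusted over the list alone, 2 at an unadjusted p under 0.05, and 0 by DESeq2 and limma (adjusted p = 0.035, and adjusted p = 0.95 with an estimated correlation).

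At 20 °C autophagy and lysosome genes were lower in hsf-1(sy441) than in N2, with 10 of 42 called over all genes and 11 adjusted over the list alone (adjusted p = 0.0048, and adjusted p = 0.43 with an estimated correlation). The yolk protein gene vit-2 had 434 fragments in replicate 3 of N2 at 34 °C, against 11 and 16 in the other 2 libraries. The yolk protein genes vit-6 and vit-5 had 206 and 56 fragments there, against at most 10 and 2. In this library 19 genes of at least 5 CPM were over 10-fold above both other libraries, among them hsp-16.21, the metallothionein gene mtl-1 and several col genes, against 0 to 8 in each of the other 17 libraries. Of 20 intestine markers 1 rose and 2 fell in heat shock of N2, also adjusted over the list alone (adjusted p = 0.90).

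A run of 28 neighbouring genes on chromosome I, from 11891590 to 12188998 (297 kb), had 25 members called higher in hsf-1(sy441) and 20 in the transgene strain than in N2 at 20 °C, and hsf-1 lay inside it. A log2 fold change above 0 was found for 28 and 27 of them. The run was defined at 20 °C as neighbours whose median over 5 genes was above 0.5 on the log2 scale in both strains against N2, among 8140 ordered genes. Its median log2 fold change was 1.60 in hsf-1(sy441) and 1.03 in the transgene strain at 20 °C, and 1.63 and 0.97 at 34 °C, while 40 flanking genes had medians of −0.13, −0.11, 0.10 and −0.04. Members were the RNA-dependent RNA polymerase gene rrf-2 with 2.01 and 1.58 and the actin regulator gene wve-1 with 1.62 and 0.88 at 20 °C. The members R06C1.4 (0.07 and 0.24 at 20 °C, −0.25 and −0.24 at 34 °C) and rbm-3.1 (0.20 and −0.05, then −0.67 and −0.86) were not raised. Extra copies with RNA in proportion would have raised these 2 genes, but RNA levels alone do not tell their copy number.

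The longest run in 1000 random orders of the genes was 5, which argues against a chance run, and without smoothing the longest real run was 9 against 5. Reads shared between overlapping genes were argued against by the 26 members with a locus of their own, whose median in the transgene strain at 34 °C was 0.97. A candidate explanation is that both strains carry extra copies of this segment, which the median of 0.97 at 34 °C goes with, but the values at 34 °C were in view when the segment was noticed. The segment was also higher in hsf-1(sy441) than in the transgene strain, 1.51-fold at 20 °C and 1.57-fold at 34 °C (25 and 26 of 28 genes), which an equal number of copies in both strains does not explain. This is a hypothesis, since no DNA was measured. A regulatory effect of sy441 on neighbouring genes was not tested.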
